A study of Mus musculus with 5 samples.

How the data were processed

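RNA from the livers of 5 mice per group was pooled and hybridised, in 1 colour (Cy3), to 5 Agilent whole mouse genome arrays, 1 array for each of the 5 groups, per the labels. Each scanner file held 45018 spots, of which 43379 were not controls, for 41174 different probes; 245 of the probes were spotted 10 times. The arrays were scanned and quantified with Feature Extraction 10.5.1.1, per the file headers, which also give the mm9 build for probe positions. The processed intensity of each spot is background-subtracted and detrended within the array, with substitute values for dim spots, per the file headers, and was deposited without scaling between arrays. The mean and local background intensity deposited for each spot are as scanned. The deposited value table is a linear ratio of each processed intensity to 1 constant per array, close to the 75th percentile of all its spots, found by setting each column against that array's scanner values. It is not centred across arrays and its direction is that of the signal, so neither scale nor centring nor direction remained unknown. Its column medians were 0.0700 in control, 0.0738 in HFHFr-N, 0.0744 in HFHFr-NA, 0.0675 in HFHFr-F and 0.0721 in HFHFr-FA. How the authors chose the constant is not given in the sources used here.

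Control, HFHFr-N, HFHFr-NA and HFHFr-F were on 1 slide and HFHFr-FA was alone on a second slide with a scan of its own. No spot was saturated. Spots marked as outliers by the software, 89 in control, 60 in HFHFr-N, 75 in HFHFr-NA, 95 in HFHFr-F and 96 in HFHFr-FA, were left out on that array. The 75th percentile of the processed signal was 173.9, 172.5, 179.8, 222.9 and 211.7 in the same order.

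For the main setting, log2 of the processed signal minus the array's 75th percentile over non-control spots was averaged over the spots of a probe. Probes were named through the RefSeq accession in the file where the RefSeq gene table, of assembly GRCm38.p6 and used for names only, held it. This named 24844 probes, and 16330 kept the file's own name, which can be old. Exon, intron and untranslated region were not determined, because no genome of that build was used here. Of 28632 gene names 8582 had several probes, and the probe with the highest mean signal over the 5 arrays stood for the gene. For the named genes, other probes measured on both arrays were set against the chosen probe. A probe counted as differing when its log2 ratio was at least 0.5 in the opposite direction, or over 1.0 away. Smaller gaps were not counted. Differing probes are reported beside the gene for Cpt1a. They were also found for Vps13a, Rdh9, Car3, Sort1, Hsd17b13, Abcd2, Ccdc71, Lss and Rsad2. A gene entered a comparison when it was well above background on at least 1 of the 2 arrays. Where the other array did not measure it, the ratio is a bound, the bright signal over the higher of the gene's own signal there and the lowest signal of any probe well above background there. A bound under 1-fold was set to a log2 ratio of 0. A gene measured on 1 array alone could therefore not be lower on that array. There were 13133 gene names well above background on all 5 arrays and 13026 on none.

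A log2 ratio was computed for each of 7 pairs of groups, and genes at least 2-fold apart were counted. With 1 array per group no test between groups, p-value or standard deviation between replicates could be had. The spots of replicated probes had a median standard deviation of 0.0863 in control, 0.0762 in HFHFr-N, 0.0745 in HFHFr-NA, 0.0744 in HFHFr-F and 0.0659 in HFHFr-FA on the log2 scale. That spread describes the spots of 1 array and leaves out differences between mice, extractions and arrays. Gene counts expected from it alone were simulated for each pair.

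There were 44 lists of genes, 27 of pathways and 17 of cell type markers. Of 1008 listed symbols 986 matched a gene name. The lists hold 889 different genes, of which 83 stand in more than 1 list. Each list with at least 5 measured genes was described by its median log2 ratio and by that median's percentile among 10000 random lists of the same size matched on mean signal in 20 bins. This treats genes as independent and describes only these arrays. A list was said to stand apart outside the middle 95% of those random medians. Genes were named by a rule. In HFHFr-F against control, HFHFr-FA against HFHFr-F, HFHFr-N against control and HFHFr-NA against HFHFr-N it took the 10 highest and 10 lowest ratios among genes with a proper symbol measured on both arrays, and the 3 highest and lowest bounds. In HFHFr-N against HFHFr-F it took 5 and 5. It added up to 4 members with the largest absolute ratio from each list, and Lepr, Cyp26a1, Rarb, Srebf1, Fasn, Scd1, Cpt1a, Igfbp1, Igfbp2, Pparg, Cidec, Socs3, Saa1 and Cyp7a1 in every comparison. Pck1, also in the rule, was not analysed here. The text gives part of the named genes. The groups, comparisons, lists, rule and 9 kinds of alternative were fixed before the data were examined.

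The alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization, median centring, cyclic loess, only genes measured on both arrays, no detection filter, the mean of all probes, the deposited value table and a 3-fold threshold. Chosen after seeing the data were 3 more: the 75th percentile over probes well above background on all arrays, only names matched to RefSeq, and leaving out bright spots that lie side by side. For the last, a spot counted when it was well above background and at least 2-fold brighter than on every other array, with at least 2 other such spots within 60 scanner pixels, and 1000 random placements gave the expected numbers. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

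The steps were tested on simulated data with spot noise only, in which 200 genes had known ratios. In HFHFr-F against control 64 of 67 genes simulated at 3-fold were found at least 2-fold apart, 66 of 66 at 5-fold and 1 of 67 at 1.5-fold, and so were 36 of 13154 genes with no difference. Of 200 lists of 20 genes with no shift 2.50% stood apart in the same comparison and 6.00% in HFHFr-N against HFHFr-F, the largest share, and so did 100.0% of those shifted by 0.5 in each.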

Results

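Liver gene expression was measured in male C57BL/6J mice, a common inbred laboratory strain, at 25 weeks of age. The 5 groups were an untreated control, HFHFr-F (high-fat, high-fructose diet for 20 weeks), HFHFr-N (that diet for 16 weeks, then normal diet for 4 weeks), HFHFr-FA (16 weeks, then 4 weeks of the same diet with all-trans retinoic acid) and HFHFr-NA (16 weeks, then 4 weeks of normal diet with all-trans retinoic acid). All-trans retinoic acid is the active form of vitamin A that binds the nuclear retinoic acid receptors. Per the labels, HFHFr-F mice had severe insulin resistance and HFHFr-N mice were insulin resistant, while HFHFr-NA mice had recovered and HFHFr-FA mice were not insulin resistant and had slight steatosis. Each group was 1 array hybridised with RNA pooled from 5 mice. No difference reported here has a replicate check, no test between groups was run, and "higher" and "lower" describe these pools. Of the 43379 non-control spots, 46.7% were well above background in control, 48.4% in HFHFr-N, 49.0% in HFHFr-NA, 48.3% in HFHFr-F and 49.4% in HFHFr-FA, and the small number of arrays limits the precision.

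HFHFr-F was compared with control to describe the liver after the whole period on the diet. The HFHFr-F pool had higher signal for genes of lipid synthesis, of macrophages that take up lipid, of inflammation and of collagen matrix, and lower signal for genes typical of male liver and of periportal hepatocytes. Thrsp, a regulator of lipogenesis, had the highest log2 ratio among genes measured on both arrays, 5.06 (33.4-fold). Trem2, a lipid-sensing receptor of macrophages, was higher by 4.22 and Col1a1, a chain of type I collagen, by 4.12. Hsd3b4, a gene of steroid metabolism, had the lowest ratio among genes measured on both arrays, -5.94. Its relative Hsd3b5 was not well above background in HFHFr-F, with a log2 ratio of -6.44 or lower. These 2 probes lie on chromosome 3 at 98303072 to 98303131 and 98422848 to 98422907 (mm9), and signal shared between such close relatives was not separated. The Thrsp probe lies on chromosome 7 at 104565562 to 104565621, Trem2 on chromosome 17 at 48491522 to 48491581 and Col1a1 on chromosome 11 at 94813075 to 94813134. In total 787 of 14629 measured genes were at least 2-fold higher and 473 at least 2-fold lower.

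Of 10 measured markers of lipid-associated macrophages, 8 were higher, 0 lower and 2 under 2-fold, with a median log2 ratio of 2.48. Itgax, an integrin of dendritic cells and macrophages that was not well above background in control, was higher by at least 3.82, Cd63, a lysosomal membrane protein, by 3.44 and Spp1 (osteopontin) by 2.98. Spp1 also counts in the inflammation and cholangiocyte lists, and 5 of the 12 listed macrophage genes stand in another list. Among 26 inflammation genes 16 were higher and 0 lower, with a median of 1.22. Probes of Ccl7 and Cx3cr1, both in this list, were bright spots beside other such spots on the HFHFr-F array. The chemokine Ccl2 was higher by 3.30 and Ccl4, not well above background in control, by at least 3.28. Matrix genes had a median of 0.98, with 14 of 30 higher, including Col3a1 at 3.29. In control, 7 lipid-associated macrophage genes, 20 inflammation genes and 23 matrix genes of these lists were well above background. The other measured members entered as bounds and could not be lower. Major histocompatibility complex class II genes had a median of 1.01 (5 of 9 higher) and Kupffer cell and macrophage markers 0.92 (5 of 17). Cholangiocyte markers had a median of 0.98 and T and NK cell markers 0.46, while endothelial markers had a median of 0.04 with 14 of 14 under 2-fold. Erythroid markers had a median of 0.71, with 0 of 7 reaching 2-fold.

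Genes of fatty acid and triglyceride synthesis had a median of 0.47, with 7 of 24 higher and 0 lower. Srebf1, the transcription factor that drives lipogenesis, was higher by 1.93 and Fasn (fatty acid synthase) by 1.04, while Scd1 (stearoyl-CoA desaturase) had a ratio of 0.55. Cholesterol synthesis genes had a median of 0.66, with 7 of 25 higher, including Sqle (squalene epoxidase) at 2.35. In the list of lipid droplet genes 9 of 24 were higher and 0 lower, among them Cidea at 2.23 and Cidec at 1.07, both proteins of the droplet surface. The glycolysis list had a median of 0.44. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was higher by 1.05, while the bile acid list as a whole had a median of -0.44, led by the transporter Slco1a1 at -3.29. Cpt1a, which carries fatty acids into mitochondria, had a ratio of 0.06, its other probe gave -0.59, and the mean of its probes was -0.26.

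Sex-biased genes were apart in opposite directions. Of 23 male-biased genes that depend on growth hormone 12 were lower and 0 higher (median -1.02), and of 24 female-biased genes 11 were higher and 3 lower (median 0.83). Cyp2b9 and Cyp2b13, related cytochrome P450 genes expressed mainly in female liver, were higher by 4.58 and 4.42. Igfbp2, which binds insulin-like growth factors, had a ratio of -2.85. Acute phase genes had 9 of 28 members higher, with Saa1, a serum amyloid, at 2.93 and Lcn2 (lipocalin 2) at least 32.5-fold higher. Cyp26a1, the enzyme that degrades retinoic acid and is induced by it, was lower by a ratio of -2.48; the retinoid list had a median of 0.33 with 3 higher and 3 lower of 28. Lepr, the leptin receptor, was not well above background in HFHFr-F, with a bound of -0.97, and the leptin and STAT3 list had a median of -0.02.

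Of the 40 lists with at least 5 measured genes, 23 had medians above and 5 below the middle 95% of medians of random lists matched on expression. About 5% would lie outside if genes varied independently. Genes of a list can vary together between pools, and without replicate pools the share to expect from such variation is not known. These counts describe the arrays and cannot be set against chance. The median of all genes was -0.10, and 62.5% of the 2-fold genes were higher, against 74.2% (991 and 344 genes) after cyclic loess and 49.9% (1558 and 1564 genes) without a detection filter; with normexp background and quantile normalization the counts were 335 and 142. In simulation under the main setting, spot noise alone gave 49 higher and 29 lower genes.

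**Figure D1:**
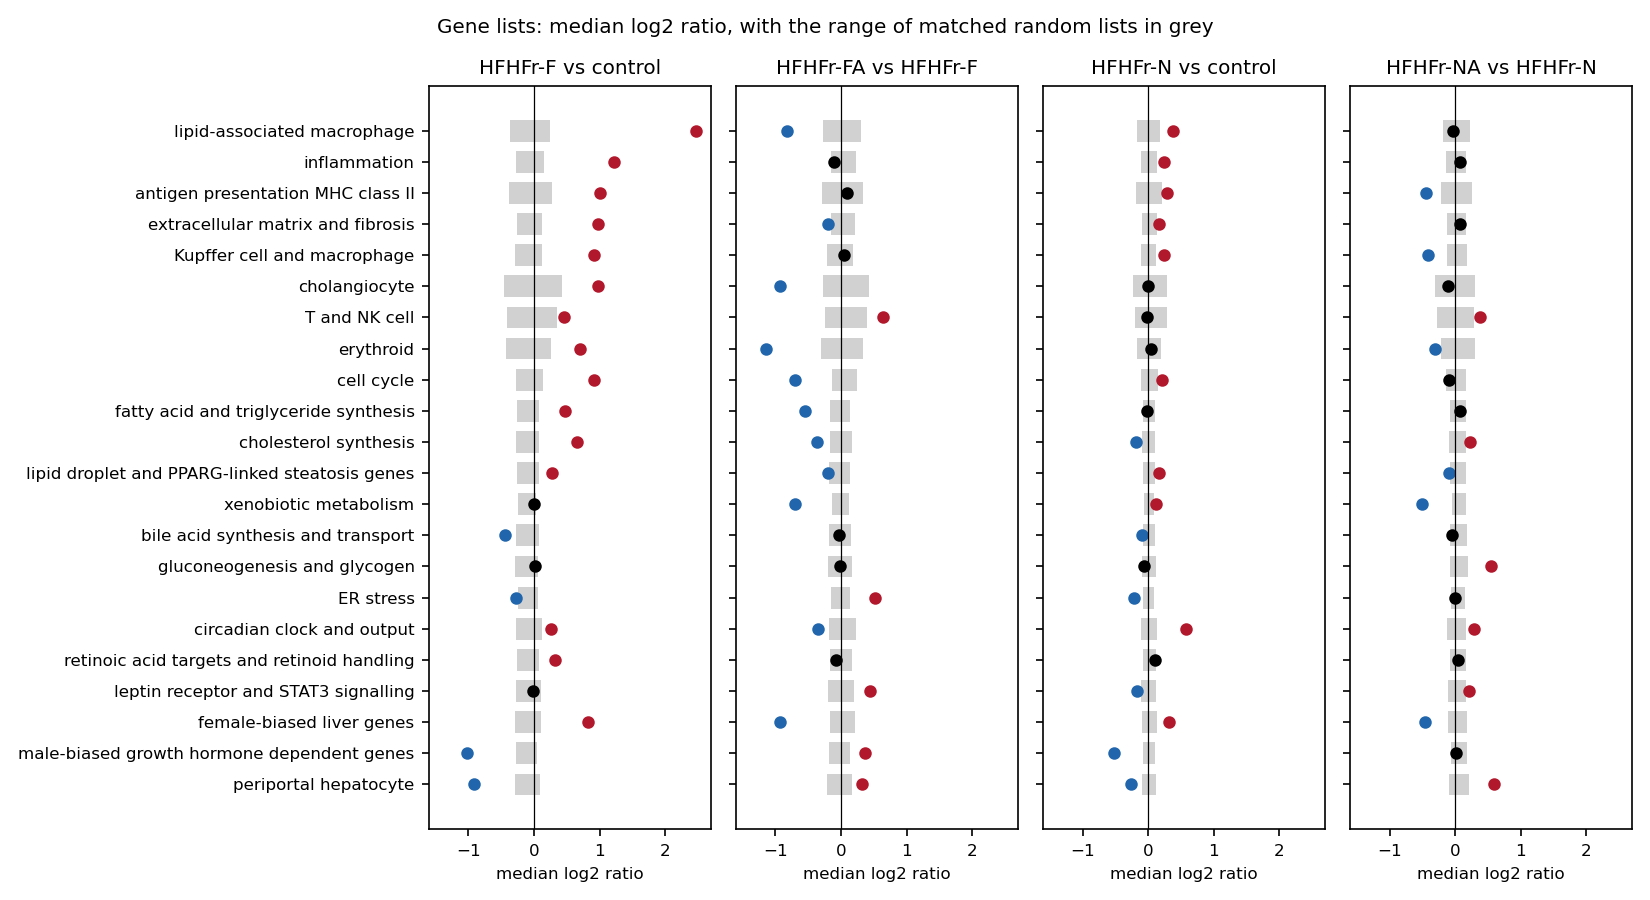
Median log2 ratio of 22 gene lists in 4 comparisons, 1 array per group. Points are list medians (red above, blue below and black within the grey bar, which spans the middle 95% of the medians of matched random lists); lipid-associated macrophage markers reached 2.48 in HFHFr-F against control and -0.82 in HFHFr-FA against HFHFr-F.

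HFHFr-FA was compared with HFHFr-F for the effect of adding all-trans retinoic acid while the diet went on. Lipogenic genes and xenobiotic enzymes were lower in the HFHFr-FA pool, and several genes linked to insulin and growth hormone were higher. Scd1 had a ratio of -3.02 and Thrsp -3.77, and of 24 fatty acid and triglyceride synthesis genes 5 were lower and 0 higher (median -0.55). Srebf1 had a ratio of -1.20, Fasn -0.71 and Pparg, the nuclear receptor that promotes fat storage, -0.81. Igfbp2 was higher by 2.47 and Igfbp1, which insulin normally represses, by 2.30. Hsd3b4 was higher by 4.33 and Slco1a1 by 2.91. The probes lie on chromosome 19 at 44469387 to 44469446 for Scd1 and on chromosome 1 at 72898677 to 72898736 for Igfbp2. In total 415 of 14925 measured genes were at least 2-fold higher and 419 lower.

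Cyp26b1 (chromosome 6, 84521952 to 84522011) and Cyp26a1 (chromosome 19, 37775566 to 37775625), both enzymes that degrade retinoic acid, were higher by 2.13 and 1.12, while Rarb, a retinoic acid receptor that is itself a target, had a ratio of -0.08. The retinoid list had 3 of 29 genes higher, 0 lower and a median of -0.07, within the range of random lists. Of 35 xenobiotic metabolism genes 13 were lower and 0 higher (median -0.71), including the glutathione transferase Gsta2 at -2.74 and the cytochrome Cyp3a11 at -1.85. Female-biased genes were lower in 10 of 24 cases and higher in 0 (median -0.93), and male-biased genes higher in 9 of 23 and lower in 1 (median 0.36). Lepr was measured in HFHFr-FA and not well above background in HFHFr-F, a bound of 1.63. The leptin and STAT3 list had a median of 0.45, with the signalling inhibitor Socs2 at 1.80. Socs2 also counts in the male-biased list. Genes of endoplasmic reticulum stress had a median of 0.52, with 6 of 30 higher and 1 lower, including the chaperone cofactors Creld2 at 1.73 and Manf at 1.33; the same list had a median of -0.28 in HFHFr-F against control, below the random range, with 4 lower and 2 higher, and 0.23 in HFHFr-FA against control.

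Among cell type markers, 4 of 10 lipid-associated macrophage genes were lower and 0 higher (median -0.82, with Spp1 at -2.59 and Trem2 at -1.39), and cholangiocyte markers had a median of -0.93. Kupffer cell and macrophage markers had a median of 0.05, class II genes 0.09 and T and NK cell markers 0.64. Matrix genes had a median of -0.20, with 5 of 31 lower, including Col1a1 at -1.72, and 1 higher. The higher one, Eln at 1.71, was a bright spot beside other such spots on the HFHFr-FA array. Stellate cell markers had a median of 0.50, above the random range. Erythroid markers had a median of -1.15, with 4 of 7 lower, including the haemoglobin gene Hba-a1 at -1.36. Cyp7a1 had a ratio of -1.98 and Hamp, the iron hormone hepcidin, was higher by 2.49. Hamp also counts in the acute phase list, which had a median of 0.35, above the random range, with 6 of 28 higher and 0 lower. Genes of the circadian clock had a median of -0.36, with Dbp, a clock output factor, at -1.81 and Arntl, a core clock activator, at 1.44; the list median was 0.04 with the mean of all probes of each gene.

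HFHFr-FA was the single array on a second slide, so slide and group cannot be told apart in this comparison. Of the 2-fold genes 49.8% were higher, against 35.9% (296 and 529 genes) after median centring and 39.7% (331 and 502 genes) after cyclic loess; normexp with quantile normalization gave 134 and 151. In simulation under the main setting, spot noise alone gave 70 and 52.

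HFHFr-N was compared with control for what differed 4 weeks after the return to normal diet. The pools were closer than in any other pair of arrays, with 166 genes higher and 121 lower among 14506. Among genes measured on both arrays Cyp2b9 and Cyp2b13 had the highest ratios, 3.04 and 2.92, with Osbpl3, an oxysterol-binding protein, at 2.41 and the droplet protein Cidea at 2.09. Asns (asparagine synthetase), an amino acid response gene, had a ratio of -2.61 and Egfr, the epidermal growth factor receptor, -1.84. Srebf1 was higher by 1.72 and Saa1 by 1.63, while Scd1 (0.21), Fasn (-0.26) and Cyp26a1 (-0.08) differed by under 2-fold. Igfbp1 had a ratio of -1.49, Igfbp2 -0.91 and Lepr, again not well above background on the treated array, a bound of -0.88.

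Male-biased genes had a median of -0.52 (3 of 23 lower) and female-biased genes 0.32 (5 of 20 higher). Lipid-associated macrophage markers had a median of 0.39, with 3 of 8 higher, and the inflammation list 0.24, with 1 of 21 higher, the chemokine Cxcl1 at 1.89. Markers of Kupffer cells and macrophages (0.24), stellate cells (0.28), B and plasma cells (0.40) and adipocytes (0.39) were also above the random range. So were pericentral hepatocyte markers (0.18), while general hepatocyte (-0.21) and periportal (-0.27) markers were below it. Cholesterol synthesis genes had a median of -0.19 and targets of PPARA, the receptor that drives fatty acid oxidation, -0.14, with Pdk4, a pyruvate dehydrogenase kinase, at -1.29. Clock genes had a median of 0.58, led by the bound for Arntl of -2.50, with the clock outputs Ciart at 2.32 and Dbp at 1.35. In all, 17 lists had medians above and 10 below the range of random lists, out of 40.

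Several large ratios came from spots that were bright on 1 array alone and lay beside other such spots. On the HFHFr-N array these included Zfp101 (2.55) and the bounds of Olfr1387 (4.02) and Gpr21 (2.75), and on the control array the bounds of Ms4a12 (-2.98) and Cacnb2 (-2.24). Against the 166 and 121 genes of the main setting, spot noise alone gave 49 higher and 29 lower in simulation. Normexp with quantile normalization, for which noise was not simulated, gave 47 and 31.

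HFHFr-NA was compared with HFHFr-N for the effect of all-trans retinoic acid given with normal diet. Here 224 genes were higher and 195 lower among 14872. Of 27 genes in the retinoid list 4 were higher, 0 lower and 23 under 2-fold, and the median of 0.04 lay within the range of random lists. Cyp26b1 had a ratio of 3.06, Cyp26a1 1.40 and Rarb 1.19. Scd1 had a ratio of -2.32 and Igfbp1 was higher by 1.68, while the list of fatty acid synthesis genes had a median of 0.08. Asns was higher by 3.13 and the aminotransferase Got1 by 2.20.

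Periportal hepatocyte genes had a median of 0.60, with 4 of 16 higher and 1 lower, among the higher ones the urea cycle enzyme Cps1 at 1.07. Genes of gluconeogenesis and glycogen had a median of 0.55, and 18 of 18 were under 2-fold. Xenobiotic metabolism genes were lower in 7 of 35 cases and higher in 0 (median -0.50), and female-biased genes lower in 5 of 22 (median -0.46), with Cyp2b13 at -1.87. Class II genes (-0.44) and Kupffer cell and macrophage markers (-0.42) also had medians below the random range, with 0 members lower by 2-fold. Interferon response genes (-0.19) and erythroid markers (-0.31) were below it too, while T and NK cell markers (0.37) were above it. Lepr had a bound of 0.69, Srebf1 a ratio of -0.67, Cpt1a 0.61 and Igfbp2 0.75. Bright neighbouring spots carried Cped1 (2.17) and the bounds of Syt14 (3.28) and Slc25a34 (2.98) on the HFHFr-NA array, and Zfp101 (-2.84), Exoc6b (-2.29) and the bounds of Olfr1387 (-4.22), Gpr21 (-2.94) and Tfap2c (-2.37) on the HFHFr-N array. Against the 224 and 195 genes of the main setting, spot noise alone gave 50 and 47 in simulation. Normexp with quantile normalization, for which noise was not simulated, gave 50 higher and 43 lower.

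**Figure D2:**
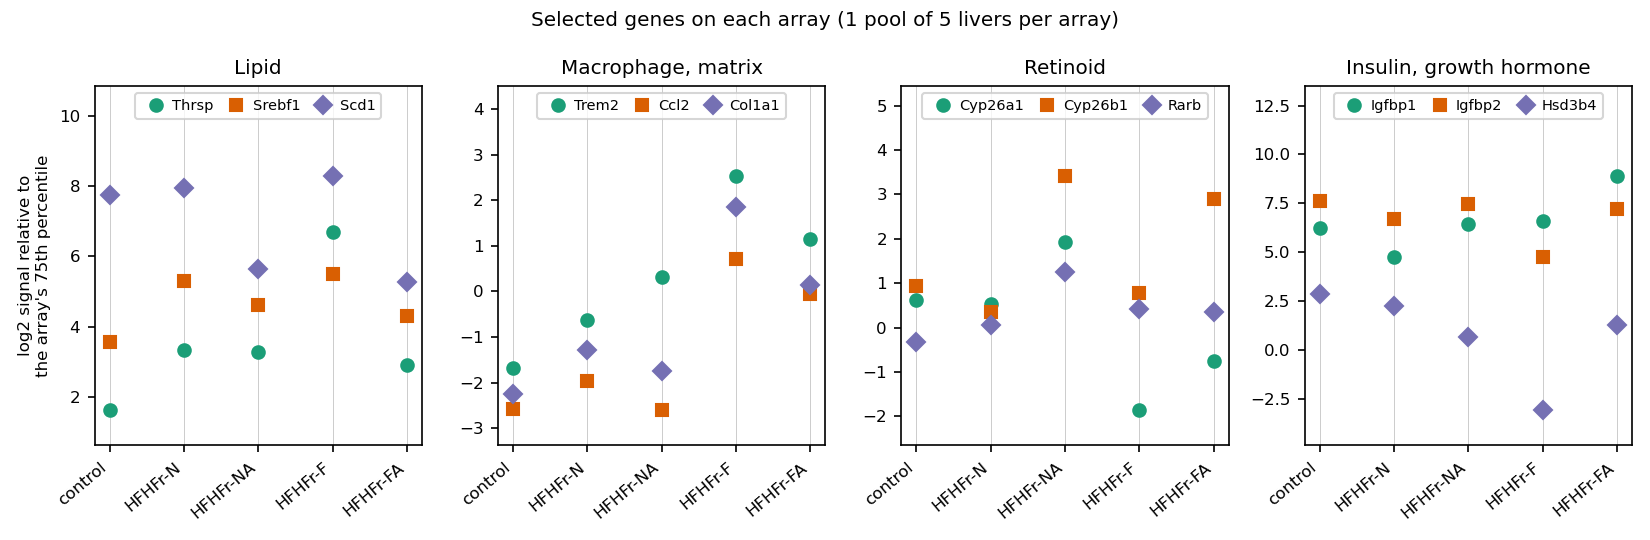
log2 signal of 12 genes on the 5 arrays, relative to each array's 75th percentile, with 1 point per gene and array. Cyp26b1 stood at 3.42 in HFHFr-NA and 2.90 in HFHFr-FA against 0.93 in control, and Scd1 at 5.63 and 5.27 against 7.74.

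The contrasts of HFHFr-FA with HFHFr-F and of HFHFr-NA with HFHFr-N share no array, and their log2 ratios correlated across 13131 genes with Pearson's r = 0.255 (95% bootstrap interval over genes 0.227 to 0.281) and Spearman's rho = 0.23. Genes are not independent replicates. Among 14274 genes measured in both, 34 were higher in both, where independent lists would share 4.29, and 41 were lower in both, where 3.80 would be shared. The shared higher genes included Cyp26a1, Cyp26b1, Igfbp1, Got1, the stress gene Gadd45g and the urea cycle gene Asl, and the shared lower genes Scd1, Cidea, Cyp2b13, Cyp3a11 and Gsta2. Opposite directions were seen for 13 genes higher with retinoic acid on the HFHFr diet and lower on normal diet, and for 14 the other way (3.87 and 4.21 from independent lists). With normexp and quantile normalization 12 and 16 genes were shared, and without the detection filter 148 and 124.

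**Figure D3:**
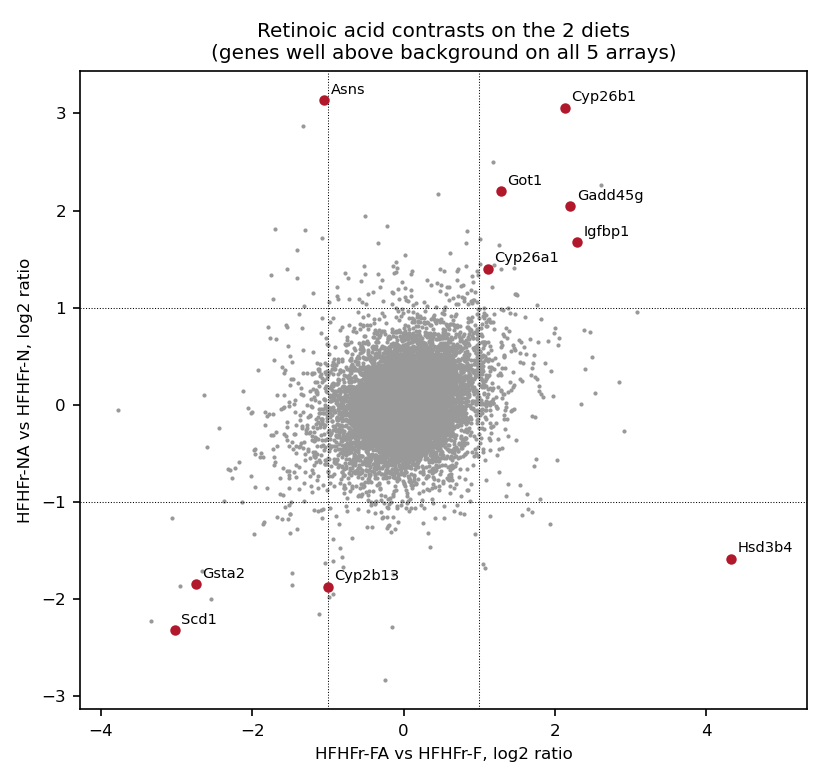
log2 ratio of HFHFr-FA against HFHFr-F (x axis) and of HFHFr-NA against HFHFr-N (y axis), 1 point per gene well above background on all 5 arrays, with dotted lines at 2-fold. Cyp26b1, Igfbp1 and Gadd45g lie in the upper right and Scd1 and Gsta2 in the lower left, while Hsd3b4 (4.33 and -1.58) and Asns (-1.05 and 3.13) lie in opposite corners.

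HFHFr-N was compared with HFHFr-F for the return to normal diet against staying on the diet. The HFHFr-N pool had lower signal for macrophage, inflammatory, matrix and cholesterol synthesis genes. Lipid-associated macrophage markers were lower in 7 of 10 cases (median -2.20), inflammation genes in 13 of 26 (-0.97), matrix genes in 12 of 30 (-0.83) and cholesterol synthesis genes in 10 of 25 (-0.85), each with 0 members higher. In HFHFr-N against control only 8, 21 and 25 genes of the first 3 lists were measured. Members measured in HFHFr-F alone entered as bounds and could not be higher, so part of these counts and medians was fixed in advance. The inflammation genes Ccl7 and Cx3cr1 had probes among the bright neighbouring spots of the HFHFr-F array. Cholangiocyte markers (median -1.14, 5 of 9 lower), Kupffer cell and macrophage markers (-0.61), T and NK cell markers (-0.57, 3 of 12 lower) and erythroid markers (-0.44, 0 of 7 lower) were also below the random range. Cdkn1a, an inhibitor of the cell cycle, had the lowest ratio among genes measured on both arrays, -4.06, followed by Ubd, a ubiquitin-like protein, at -3.65, and Thrsp at -3.36. Hsd3b4 was higher by 5.32, Slco1a1 by 2.80 and Nr1d1, a clock repressor, by 2.76. Male-biased genes had a median of 0.52 and periportal genes 0.40. Lepr was not well above background on either array. In total 317 genes were higher and 538 lower among 14799, so 37.1% of them were higher, against 25.9% (231 and 661) after median centring, 24.4% (219 and 677) after cyclic loess and 54.7% (1494 and 1238) without a detection filter. Normexp with quantile normalization gave 76 and 192, and the median of all genes was 0.10.

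Against control, HFHFr-FA had 665 genes higher and 284 lower among 14795 (70.1% higher, against 53.2%, or 1460 and 1286 genes, without a detection filter), and HFHFr-NA had 295 higher and 209 lower among 14725. Class II genes were higher in 8 of 9 cases in HFHFr-FA (median 1.17), inflammation genes in 14 of 23 (1.06) and lipid-associated macrophage markers in 4 of 9 (0.99). Acute phase genes were higher there in 10 of 28 cases and lower in 0 (0.54), with Saa1 at 3.91. Markers of T and NK cells (median 0.93, 5 of 12 higher), Kupffer cells and macrophages (0.89), adipocytes (0.88), stellate cells (0.77), neutrophils (0.63) and endothelium (0.33) were also above the random range, and erythroid markers (-0.44) below it. In control, 20 inflammation, 7 lipid-associated macrophage, 9 T and NK cell and 2 neutrophil genes of these lists were well above background. The other measured members entered as bounds and could not be lower. The adipocyte list shares genes with the lipid droplet list. Xenobiotic genes were lower in 13 of 35 and higher in 2 (-0.69), with Cyp3a11 at -3.55. In HFHFr-NA the inflammation list had a median of 0.30, class II genes -0.06 and interferon response genes -0.40. Normexp with quantile normalization gave 191 and 74 for HFHFr-FA and 62 and 65 for HFHFr-NA.

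To follow the genes of the diet without a shared array, those 2-fold apart between HFHFr-F and HFHFr-N were taken up in HFHFr-FA against control. Of the 538 genes higher in HFHFr-F 492 had a ratio there, with a median log2 ratio of 0.98 and 241 still 2-fold higher. Of the 317 lower genes 272 had one, with a median of -0.56 and 66 still 2-fold lower. Genes well above background on neither array were left out. A gene measured on 1 array alone entered as a bound and could not be lower on that array. No array serves both for the choice and for the follow-up, so noise in the choice does not carry over. The bounds and the genes left out can still tilt these medians and shares. Of the 787 genes higher in HFHFr-F than in control, 181 of the 758 measured were 2-fold higher in HFHFr-FA than in HFHFr-N and 30 lower (median 0.55), and the 473 lower genes had a median of -0.15, again with no shared array. Where an array is shared, noise in the choice pulls the ratios, by an amount not estimated for these genes. In simulation with spot noise only, 49 genes came out higher and 29 lower in HFHFr-F against control. Followed up, they had medians of 0.61 and -0.43 with the control shared, and of -0.59 and 0.42 with HFHFr-F shared. Those genes were chosen by noise alone, so their medians do not give the pull on the 787 and 473 genes. With the control shared, the 787 genes had a median of 0.98 in HFHFr-FA against control (358 of 748 still 2-fold higher) and the 473 genes -0.58. With HFHFr-F shared, in HFHFr-FA against HFHFr-F, 228 of the 787 were 2-fold lower and 4 higher (median -0.58), and of 419 of the lower genes 152 were 2-fold higher and 5 lower (median 0.81). Across genes, the ratios of HFHFr-F to control and of HFHFr-N to control had r = 0.575 and a covariance of 0.102. Simulated spot noise through the shared control gave r = 0.494 and a covariance of 0.0161. Those of HFHFr-F to control and HFHFr-FA to HFHFr-F had r = -0.561 and a covariance of -0.149, where noise gave r = -0.483 and a covariance of -0.0163. The simulated noise leaves out differences between mice, extractions and arrays, which a shared array also carries into both values.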

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

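The tests of the explanations given here for patches, cell types and the slide were chosen after the results were seen. None of the differences between diets listed first was tested, since each contrast is 1 array against 1 array.

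Some genes were at least 2-fold apart in opposite directions with all-trans retinoic acid on the HFHFr diet (HFHFr-FA against HFHFr-F) and on normal diet (HFHFr-NA against HFHFr-N). Hsd3b5 had log2 ratios of 4.89 or more and -1.52, a difference of 6.41 or more, and Hsd3b4 4.33 and -1.58, a difference of 5.91. Signal shared between these close relatives was not separated. Serpina4-ps1, a pseudogene of the serpin family, had 2.88 or more and -1.15 (4.04 or more), Vps13a 1.94 and -1.23 (3.17) and the adipokine Cfd 1.05 and -1.64 (2.69). The other direction was seen for Taf15 at -1.33 and 2.87 (difference -4.20), Asns at -1.05 and 3.13 (-4.18), Tff3 at -1.70 and 1.81 (-3.51), Apoa4 at -1.41 and 1.59 (-3.00) and the transferrin receptor Tfrc at -1.31 and 1.01 (-2.33). Among lists, cholesterol synthesis had medians of -0.37 and 0.23 (difference -0.59) and the circadian clock -0.36 and 0.28 (-0.64). With the mean of all probes of each gene the clock median on the HFHFr diet was 0.04, so the opposite directions of that list hung on the choice of probes. Other Vps13a probes gave HFHFr-F against control ratios of -0.09 to 0.20 where the chosen probe gave -2.64.

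A first pattern is that 828 spots were well above background and at least 2-fold brighter on 1 array than on every other, 577 of them not well above background elsewhere. They formed 398 close pairs where random placement gave 99.1, with more pairs than the upper bound of random placements on 5 of 5 arrays, most in HFHFr-NA (153 against 21.7). Spots dim on 1 array alone formed 19 close pairs where random placement gave 13.3, above the bound on 0 arrays. Local patches of raised signal may therefore be a source of the spots lying side by side, and expression in that group alone would not place 213 spots in patches where random placement gave 21.0. For the 615 other spots a difference in expression stays open and untested.

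The second pattern is that markers of several other cell types were higher in HFHFr-F than in control. A lower share of hepatocytes would raise all of them alike, but the median of lipid-associated macrophage markers lay 2.44 above that of endothelial markers, with no overlap of the quartiles. More blood of unchanged cell composition would raise these macrophage markers no more than the erythroid markers. The macrophage median lay 1.77 above the erythroid median, again without overlap, which argues against that. A larger share of white cells in the blood cannot be judged from the erythroid markers and was not tested. For the Kupffer cell markers, 0.21 above the erythroid median, more blood cannot be told apart, because the quartiles overlap. More cells of some types and more expression per cell may each contribute, and neither was tested; 7 of the 12 lipid-associated macrophage genes were well above background in control liver.

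The third pattern is the difference between HFHFr-FA and HFHFr-F, with the former alone on its slide. The slide as the whole cause was argued against: genes 2-fold higher there had a median of 0.30 in HFHFr-NA against HFHFr-N, which share a slide, and genes 2-fold lower -0.23, a difference of 0.54 (95% bootstrap interval over genes 0.45 to 0.65). The slide as part of the cause cannot be told apart from the group, since 834 genes lay 2-fold apart between these arrays while pairs on 1 slide ranged from 287 to 1260. An effect of all-trans retinoic acid stays open and was not tested.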

How the results depend on the processing

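Results with only RefSeq-matched names, with the 75th percentile over detected probes and without patches of bright spots were chosen after seeing the data. No paired analysis was possible because each group is 1 array, and for the same reason no replicate was left out and no slide block fitted.

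Under the scalings by quantile, median, cyclic loess, detected probes and the deposited value table, the mean of all probes and without patches, all 14 counts of genes stayed within 1.5-fold. In the 5 main comparisons 122 list medians stood outside the random range; the lists of HFHFr-FA and HFHFr-NA against control were not run under the alternatives. All 122 stayed outside on the same side under median centring, the value table, detected probes and without patches, 118 under cyclic loess, 116 under quantile, 115 for both arrays, 113 without filter and for the mean of probes, 112 for RefSeq names and 111 for normexp. The sizes held less well. Without a turn of sign, list medians shifted by at least the spot standard deviation of the log2 ratio (0.099 to 0.115) in 45 of 122 cases under normexp, 28 under cyclic loess, 20 without filter, 15 under median centring, 14 for the mean of probes, 11 for both arrays, 8 under quantile and 7 for RefSeq names. Of 179 ratios of named genes 119 shifted as much under normexp, 30 under cyclic loess, 30 for the mean of probes, 25 without filter, 14 under quantile and 11 under median centring.

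Counts are given as higher and lower. For HFHFr-F against control they were 335 and 142 under normexp with quantile normalization, 1558 and 1564 without the filter and 262 and 122 at 3-fold. HFHFr-FA against HFHFr-F gave 134 and 151, 1284 and 1186, and 92 and 110 in the same order. For HFHFr-N against control these were 47 and 31, 979 and 866, and 45 and 30, for HFHFr-NA against HFHFr-N 50 and 43, 1049 and 1062, and 64 and 43, and for HFHFr-N against HFHFr-F 76 and 192, 1494 and 1238, and 68 and 148. HFHFr-FA against control gave 191 and 74, 1460 and 1286, and 139 and 60, and HFHFr-NA against control 62 and 65, 1184 and 1061, and 81 and 56. With both arrays above background, counts were 102 and 77 for HFHFr-N against control, 134 and 119 for HFHFr-NA against HFHFr-N and 187 and 130 for HFHFr-NA against control. With RefSeq names only, higher counts were 239 for HFHFr-FA against HFHFr-F, 129 for HFHFr-NA against HFHFr-N, 185 for HFHFr-N against HFHFr-F and 187 for HFHFr-NA against control, and lower counts 278, 76, 180 and 138 for HFHFr-F, HFHFr-N, HFHFr-FA and HFHFr-NA against control. Fewer genes, a higher threshold or more dim genes enter by construction in all but normexp. Under normexp an offset of 50 was added to every spot, where the median processed signal was 13.1 in control and 16.4 in HFHFr-FA. Such an offset shrinks the ratios of dim genes by construction. How much of the fall in counts came from it was not tested. Genes higher in both retinoic acid contrasts numbered 12 under normexp, 19 with both arrays, 21 with RefSeq names and 148 without filter, and genes lower in both 16 under normexp and 124 without filter.

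The sign turned for the xenobiotic list in HFHFr-N against HFHFr-F (0.01 in the main setting), at -0.033 under normexp, -0.042 under quantile, -0.098 under median centring, -0.093 under cyclic loess and -0.048 with detected probes. It turned for Cpt1a in HFHFr-FA against HFHFr-F (0.01), at -0.02 and -0.089 under normexp and median centring, and with the mean of probes in HFHFr-F against control (-0.263) and HFHFr-N against HFHFr-F (0.131). The adipocyte list in HFHFr-N against HFHFr-F was at 0.087 without filter, and the clock list in HFHFr-FA against HFHFr-F at 0.04 with the mean of probes. The cause was not tested. The median of all genes without filter was -0.25 in HFHFr-F, -0.25 in HFHFr-FA, -0.13 in HFHFr-N and -0.17 in HFHFr-NA against control and 0.10 in HFHFr-N against HFHFr-F. It was 0.10 there with the mean of all probes, 0.11 with the value table, and -0.10 in HFHFr-FA against control under median centring.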

Other observations

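No explanation was tested for the values given here, and the genes of the clock were picked out after their values were seen.

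Clock genes differed between arrays in opposite ways. On the log2 scale relative to the array's 75th percentile, Dbp stood at 5.54 in control, 6.88 in HFHFr-N, 6.76 in HFHFr-NA, 4.91 in HFHFr-F and 3.10 in HFHFr-FA. Arntl, which works in the opposite phase, stood at -1.18 in control, -3.32 in HFHFr-NA, -1.24 in HFHFr-F and 0.20 in HFHFr-FA, and was not well above background in HFHFr-N. Nr1d1 was at 0.08 in control and -2.87 in HFHFr-F and not well above background in HFHFr-FA. Nr1d2, a related repressor, was at 1.91, 2.47, 2.19, 1.68 and 0.88 in the same order as Dbp. The time of day at which the livers were taken is not given in the sources used here.

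Further lists are given here for HFHFr-F against control. Cell cycle genes had a median of 0.91 with 12 of 30 higher and 1 lower, including Cdkn1a at 2.68 and the proliferation marker Mki67 at 1.74. Immediate early and heat shock genes had a median of 0.31 with 9 of 31 higher, among them the stress factor Atf3 at 3.43. The interferon response list had a median of 0.33 with 7 of 31 higher and targets of NRF2, the oxidative stress factor, 0.25 with 5 of 27 higher, including the reductase Cbr3 at 2.85. Adipocyte markers had a median of 1.07 over 5 measured genes and stellate cell markers 0.30. Of the 11 adipocyte genes on the array 6 stand in another list, with Cfd, Cidec, Fabp4 and Lipe in the lipid droplet list. The adipocyte median is therefore not separate from the lipid droplet result. Periportal genes had a median of -0.92 with 7 of 16 lower and 1 higher, and general hepatocyte genes -0.48 with 2 of 10 lower. Oxidative phosphorylation genes (median -0.04, 37 of 38 under 2-fold) and gluconeogenesis genes (0.01) lay within the range of random lists.

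In HFHFr-FA against HFHFr-F, cell cycle genes had a median of -0.71 with 6 of 31 lower and 1 higher, and NRF2 targets -0.49 with 7 of 27 lower and 0 higher. Neutrophil markers had a median of 0.70 with 2 of 6 higher, and endothelial markers 0.37 with 14 of 14 under 2-fold. Only 3 neutrophil genes were measured in HFHFr-F against control. Those measured in HFHFr-FA alone entered here as bounds and could not be lower. Probes named Olfr166, Mc1r and Defb19, genes best known outside the liver, had ratios of -3.47, -3.44 and -2.70 in HFHFr-F against control and of 2.85, 2.53 and 2.40 in HFHFr-FA against HFHFr-F, the directions in which Hsd3b4 differed.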
